A study of Mus musculus with 5 samples.

How the data were processed

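RNA-seq was done on total RNA of sorted fluorescent beta cells in 5 samples, 3 in the p16 group and 2 in the GFP group, per the labels. Per the submitters' processing notes, reads were processed with TopHat2, Cuffnorm and Cuffdiff on the mm9 build. Versions, annotation, library scaling and strand handling are not given in the sources used here. The table deposited by the authors is laid out as Cuffdiff output, with 1 FPKM value per group, the log2 ratio, a test score, a p-value and a q-value per gene. FPKM is scaled by transcript length and library size, so it is not a count and no count model was run. Depth per sample is unknown, which limits how far differences among genes of low FPKM can be read. Total FPKM over genes was 439059 in GFP and 412860 in p16. These totals leave out genes listed at 0 for too many fragments, Ins1 and Ins2 in both groups and Chga in p16 only. Chga is listed at 8261 FPKM in GFP, so the totals are not a like comparison of the groups.

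Of 23951 genes, 13264 had been tested by the authors, 10679 were not tested, 6 carried a status for too many fragments and 2 had failed. The deposited q-values equalled Benjamini-Hochberg values over the tested genes within 5.23e-07. The smallest p-value was 5e-05, shared by 271 genes, and its q-value was 0.00245. The log2 ratio was recomputed from the FPKM values, since 449 cells of the deposited column hold text; it differed by over 0.001 in 1 of 16930 genes. Starts were counted from 0 in the table, as the lengths of 294 of 300 microRNA genes showed, and 1 was added. Coordinates span the locus of a gene as the table gives it, which can hold overlapping genes.

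Before the data were examined, limma on log2(FPKM + 1) per sample was planned, with camera for lists. Group values allow no such fit, so the authors' calls at a q-value below 0.05 are described instead, as planned for that case. For lists, limma 3.58.1 cameraPR in R 4.3.3 was run on the authors' p-values turned into normal quantiles signed by direction, with a preset correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over 27 lists with at least 5 tested members of 29 fixed lists. That form of the test was chosen after the table was seen. An estimated correlation needs values per sample and was not computed. Each list's median was also placed among 10000 random lists matched in 20 bins of mean FPKM. Counts adjusted over the list alone used the authors' p-values. Ratios have no pseudocount; where a group is listed at 0 no fold is given, and in medians such a gene ranks beyond all others. On simulated quantiles for 13264 genes with lists shifted by 1, the list test recovered 100% of shifted lists and called 0.125% of lists without shifted genes. The shifted lists had 37 to 76 tested members, so recovery of smaller lists was not simulated. The simulated quantiles were independent between genes, were not capped by a smallest p-value and held no trend with GC content. The real ones follow GC content, so these rates need not hold for them.

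GC content and length came from the longest transcript of each gene in GENCODE release M21, used for sequence properties only because its build is not mm9; 99.1% of tested genes matched. Natural splines with 4 degrees of freedom each for GC content and log2 length were regressed out of the signed quantiles, of whose variance they explained 23.7%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all else.

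Named genes were fixed by rule: 9 chosen genes, the 10 largest rises and 10 largest falls on the log2(FPKM + 1) scale among called genes with a symbol, leaving out predicted and microRNA or snoRNA genes, and for each list up to 4 called members of largest change, or the 2 most abundant where fewer than 2 were called. The rule also asked that groups not overlap, which group values cannot show. Some genes that the rule selects are not reported here. Alternatives covered pseudocounts, filters on mean FPKM, scaling, thresholds and settings of the list test. Quantile normalization was done on log2(FPKM + 1), so its ratios carry a pseudocount of 1 as well. A change in the size of a ratio under it is therefore not due to the normalization alone.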

Results

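Gene expression was profiled by RNA-seq in pancreatic beta cells of transgenic mice. In 3 samples the beta cells expressed both p16INK4a, a cell cycle inhibitor that blocks the cyclin D kinases, and green fluorescent protein, and formed the p16 group. In 2 samples from control mice they expressed the fluorescent protein alone and formed the GFP group. Transgenes were induced with tetracycline for 10 days, and fluorescent cells were sorted from dissociated islets. The comparison asks which transcripts differ in beta cells in which p16INK4a is switched on. Values are the authors' FPKM, 1 per group and gene, without values per sample. The depth of each library and the spread between samples are therefore unknown, and no SD can be given. Whether 2 values differed was taken from the q-values in the authors' deposited table. The labels do not say whether each sample came from its own mouse, so these may reflect technical spread in part.

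Cdkn2a, the gene that encodes p16INK4a, had the largest rise of all named genes, from 0.657 FPKM in the GFP group to 34.6 FPKM in the p16 group, or 52.7-fold (q = 0.00245 in the authors' deposited table). It lies at chromosome 4, 88920377 to 88940523, in the mm9 build. The labels do not say whether the transgene carried the mouse or the human coding sequence. With a pseudocount of 5, the log2 ratio of Cdkn2a FPKM was 2.81 against 5.72 without one. Cdkn2b, the neighbouring gene for the related inhibitor p15INK4b, rose 2.18-fold, from 8.60 to 18.7 FPKM (q = 0.0142 in the authors' deposited table). Cdkn1a, which encodes the inhibitor p21, stood at 31.2 FPKM with GFP and 54.6 FPKM with p16 and did not pass in the authors' deposited table (q = 0.0576). Mki67, a marker of cycling cells, was low in both groups, at 1.06 and 0.881 FPKM, and did not pass (q = 0.757 in the authors' deposited table).

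Of 13264 genes tested in the authors' deposited table, 573 were higher and 146 lower with p16 at a q below 0.05. The median fold was 2.57 among the genes that rose and 2.30 among those that fell. After Cdkn2a, the largest rises on the log2(FPKM + 1) scale belonged to Vim, which encodes the intermediate filament vimentin and rose 28.0-fold, from 0.328 to 9.18 FPKM. Its log2 ratio of 4.81 was 2.94 with a pseudocount of 1 and 1.41 with a pseudocount of 5, so the size of this rise depends on how values near 0 are treated. Ifit1, an interferon-induced gene, rose 9.88-fold to 23.2 FPKM. Agpat4, an acyltransferase of phospholipid synthesis, rose 11.1-fold to 17.8 FPKM, and the kinase gene Sgk2 rose 9.10-fold to 23.7 FPKM. With a pseudocount of 5 the log2 ratios of Ifit1, Agpat4 and Sgk2 fell from 3.30, 3.47 and 3.19 to 1.94, 1.79 and 1.92. Vcl, which encodes vinculin, reached 44.5 FPKM and the syntaxin gene Stx11 reached 11.7 FPKM. Tnfrsf12a, a receptor of the tumour necrosis factor family, reached 62.2 FPKM and Pdlim7, an actin-associated protein, reached 31.7 FPKM. Tnfrsf12a and Pdlim7 each share their locus with other genes, as do Rasd1, Cxcl10, Cxcl16, Gadd45a, Kcnk3, Lss, Ppard, Ctrb1, Hbb-bs, Nfkb2 and Xist, so the split of reads there is uncertain.

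The largest falls included immediate early genes, which respond fast to stimuli. Fos, a transcription factor of the AP-1 complex, fell 6.36-fold, from 599.9 to 94.3 FPKM. Gem, a small GTPase, fell 4.51-fold to 46.0 FPKM and Btg2 fell 4.26-fold to 86.3 FPKM. Rasd1, Egr1 and the phosphatase gene Dusp1 fell to 50.04, 61.3 and 41.1 FPKM. Tnfaip3, an inhibitor of NF-kappaB signalling, fell 3.77-fold to 18.2 FPKM. The heat shock genes Dnajb1, Hspa1a and Hspa1b fell to 45.7, 5.72 and 5.73 FPKM. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain.

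**Figure D1:**
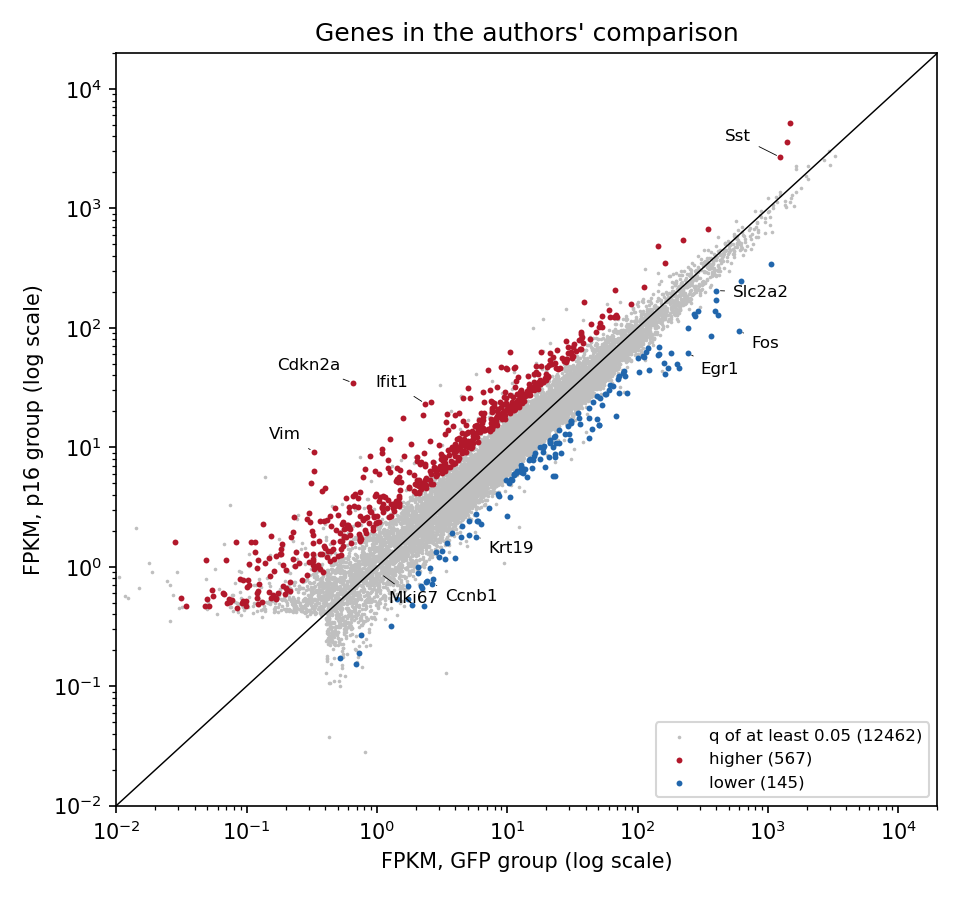
Each point is a gene tested by the authors with FPKM above 0 in both groups, with its GFP value on the horizontal log axis and its p16 value on the vertical log axis. Red points are called higher and blue points lower with p16 at a q below 0.05, and the line marks equal values; Cdkn2a and Vim lie far above it, Fos and Egr1 below it.

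The calls followed the genes' GC content and abundance. Genes called higher had a median transcript GC content of 53.8%, against 43.6% for genes called lower and 49.99% for the other tested genes. With the tested genes parted by GC content into 5 bins of equal size, 45 were higher and 80 lower in the lowest bin, and 217 were higher and 13 lower in the highest. Across genes, which are not independent replicates, the signed quantile of the authors' p correlated with GC content at a Spearman rho of 0.47. Among genes with a mean FPKM below 1 the authors' deposited table had 102 higher and 6 lower, while at 100 FPKM or more it had 12 higher and 22 lower. Once a smooth trend with GC content and transcript length was removed, 386 genes were higher and 90 lower at the same size of quantile, of which 312 and 62 were also calls of the authors. With the authors' p adjusted again over genes with a mean FPKM of at least 5, 298 were higher and 106 lower.

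**Figure D2:**
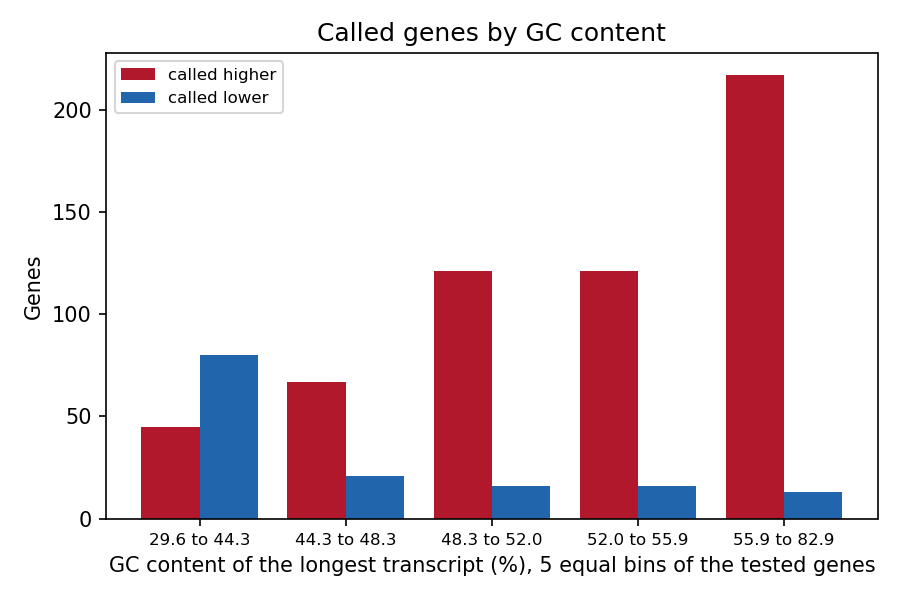
Bars give the number of genes called higher (red) and lower (blue) with p16 in the authors' comparison, in 5 bins of equal size of the tested genes by the GC content of the longest transcript in percent. Higher calls went from 45 in the lowest bin to 217 in the highest, and lower calls from 80 to 13.

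Of the 27 gene lists with enough tested members, 9 were higher and 4 lower with p16 than the other genes in limma's cameraPR. The test sets genes against genes in 1 comparison, so its adjusted p does not measure a list's spread between samples. Its size also rests on the preset correlation of 0.01. At 0.1 the adjusted p was 3.2e-05 for immediate early, 0.00401 for proliferation, 0.0013 for interferon and 0.0102 for cholesterol genes. Genes of cell proliferation fell with p16. Of 46 tested members 8 were lower and none higher in the authors' deposited table, or 15 lower when adjusted over the list alone, and 40 of the 46 had the lower value with p16. Hmgb2, a chromatin protein of dividing cells, fell from 44.7 to 14.3 FPKM, and the mitotic cyclin Ccnb1 from 2.67 to 0.716 FPKM. Top2a, a topoisomerase of dividing cells, fell from 4.43 to 1.79 FPKM, and Stmn1 from 18.9 to 9.15 FPKM, a call lost with other filters. The list's median log2 ratio was -0.77 (adjusted p = 1.39e-10). Regulators of G1 went both ways, with 3 higher and 1 lower of 20 in the authors' deposited table, or 4 and 1 adjusted over the list alone. Ccnd1, the cyclin D1 gene, rose from 32.7 to 72.7 FPKM and Trp53 from 11.5 to 23.2 FPKM. Cdkn2c, which encodes the inhibitor p18INK4c, fell from 10.6 to 3.86 FPKM. As a list they did not pass (adjusted p = 0.595), with the test pointing up and the median log2 ratio at -0.23.

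Genes listed as secretory factors of senescence, which include receptor and adhesion genes, rose. Of 50 members listed above 0 the authors tested 27, of which 17 had a mean FPKM of at least 1 and 8 of at least 5. With the untested members included at a signed quantile of 0, the list's adjusted p in cameraPR was 0.000305. Of the 27 tested members 6 were higher and none lower in the authors' deposited table, or 13 and 1 when adjusted over the list alone. The chemokine genes Cxcl10 and Cxcl16 rose from 11.3 to 46.1 FPKM and from 0.806 to 2.55 FPKM. Plaur, the urokinase receptor gene, rose from 0.230 to 2.59 FPKM and the adhesion gene Icam1 from 2.92 to 6.54 FPKM. The median log2 ratio was 0.96 (adjusted p = 1.7e-06), or 0.56 with quantile normalization on the log2(FPKM + 1) scale. Targets of p53 went both ways, with 3 higher and 1 lower of 30 in the authors' deposited table and 6 and 3 adjusted over the list alone. Sesn2 rose from 11.4 to 47.2 FPKM and Gadd45a from 35.8 to 79.0 FPKM. Btg2, the member called lower, is also on the immediate early and dissociation stress list. That list did not pass (adjusted p = 0.595), and its median log2 ratio was -0.02.

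Interferon-responsive and antigen presentation genes rose as a group. Of 46 tested members 18 were higher and 2 lower in the authors' deposited table, or 25 and 2 adjusted over the list alone. Besides Ifit1, Isg15 rose from 0.401 to 4.59 FPKM, Rtp4 from 4.23 to 19.4 FPKM and the antiviral gene Rsad2 from 1.22 to 6.67 FPKM. The transcription factor gene Irf1 fell from 268.6 to 131.3 FPKM, and the other member that fell was Ddx60. Both were named after their values were seen. The list's median log2 ratio was 0.73 (adjusted p = 4.54e-13).

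Immediate early and dissociation stress genes fell. Of 40 tested members 21 were lower and none higher in the authors' deposited table, or 25 lower adjusted over the list alone. On the log2(FPKM + 1) scale Fos, Btg2, Egr1 and Dusp1 fell most, and the list's median log2 ratio was -1.03 (adjusted p = 2.35e-18).

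Genes of beta-cell identity did not move as a list (adjusted p = 0.517), with 2 higher and 4 lower of 37 in the authors' deposited table and 3 and 4 adjusted over the list alone. Slc2a2, the glucose transporter gene, fell from 401.7 to 205.2 FPKM, Trpm5, a cation channel, from 42.6 to 17.7 FPKM, and Npas4, an activity-dependent factor, from 50.9 to 15.5 FPKM. In stimulus-secretion coupling 2 of 46 members were higher and 1 lower in the authors' deposited table, 3 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.454). The potassium channel gene Kcnk3 rose from 1.76 to 4.61 FPKM. Ins1 and Ins2 carried no estimate: both are listed at 0 in both groups with a status that marks too many fragments to quantify.

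Markers of immature or dedifferentiated beta cells rose, with 7 higher and none lower of 21 tested in the authors' deposited table and 9 and 1 adjusted over the list alone. Aldh1a3, a retinaldehyde dehydrogenase gene, rose from 0.581 to 3.75 FPKM and the peptide YY gene Pyy from 224.7 to 544.7 FPKM. With Vim, which rose more, the list had a median log2 ratio of 1.18 (adjusted p = 1.52e-06). It was 0.36 with quantile normalization on the log2(FPKM + 1) scale. The added 1 shrinks ratios of low values by itself, so this drop is not that of the normalization alone. Genes that islets normally keep silent rose too, with 3 higher and none lower of 19 in the authors' deposited table and 7 and 0 adjusted over the list alone (adjusted p = 0.000137), though the list's median lay at percentile 92.3 of random lists of like expression. That median log2 ratio was 0.49, or 0.25 with quantile normalization on the log2(FPKM + 1) scale. Ldha and Yap1 reached 1.503 and 0.474 FPKM from 0.393 and 0.0481 FPKM. Without genes below a mean of 1 FPKM this list's adjusted p was 0.0519.

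Cholesterol and fatty acid synthesis genes rose, with 9 higher and none lower of 33 tested in the authors' deposited table and 12 higher adjusted over the list alone. Mvd, of the mevalonate pathway, rose from 9.60 to 29.2 FPKM and the sterol synthesis gene Lss from 16.1 to 35.2 FPKM. The median log2 ratio was 0.50 (adjusted p = 4.21e-07). In glycolysis 4 of 22 members were higher in the authors' deposited table, Ldha and Pfkfb3 among them, with 5 higher adjusted over the list alone (adjusted p = 0.0231). Pfkfb3, a regulator of glycolytic flux, rose from 2.04 to 5.32 FPKM. The glycolysis median log2 ratio, 0.10 or 0.19 with quantile normalization, lay at percentile 93.5 of random lists of like expression, and the list no longer passed once the GC and length trend was removed (adjusted p = 0.0627).

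Oxidative phosphorylation genes had slightly lower values with p16, in 59 of 76 members, or 38 with quantile normalization, with no single gene called in the authors' deposited table, over all genes or adjusted over the list alone. Atp5l and Atp5e, of the ATP synthase, stood at 613.8 and 468.6 FPKM with GFP and 505.0 and 444.4 FPKM with p16. The list's median log2 ratio of -0.13 passed (adjusted p = 0.0231), but lay at percentile 51.5 of random lists of like expression, and it failed without the GC and length trend (adjusted p = 0.185). Ribosomal protein genes had a median log2 ratio of -0.17 over 66 members (adjusted p = 0.00252), which turned to 0.02 with quantile normalization, with none called in the authors' deposited table or adjusted over the list alone, at percentile 29.5 of such lists. Rpl41 and Rpl38 stood at 1968 and 1510 FPKM with GFP and 1884 and 1230 FPKM with p16. Both lists failed at a preset correlation of 0.05 (adjusted p = 0.255 and 0.0957), as did glycolysis (adjusted p = 0.115). The TCA cycle list did not pass (adjusted p = 0.322), with none of 32 called in the authors' deposited table or adjusted over the list alone, and values of 500.2 and 433.5 FPKM for Acly and 249.3 and 193.0 FPKM for Mdh1.

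Several further lists did not pass while single members did. Insulin, IGF and mTOR signalling (adjusted p = 0.437) had 4 higher of 34 in the authors' deposited table, or 4 higher and 2 lower adjusted over the list alone. Its members Eif4ebp1, a translational repressor, and Ulk1, an autophagy kinase, rose from 8.90 to 47.2 FPKM and from 10.5 to 27.3 FPKM, and the amino acid transporter gene Slc7a5 from 53.5 to 102.7 FPKM. The unfolded protein response (adjusted p = 0.227) had 5 higher and 1 lower of 37 in the authors' deposited table, 9 and 1 adjusted over the list alone. Trib3 rose from 9.71 to 46.3 FPKM, Derl3 from 11.7 to 36.0 FPKM and the kinase gene Eif2ak3 from 21.3 to 61.4 FPKM. Atf3, which is also on the immediate early and dissociation stress list, fell from 616.2 to 248.0 FPKM. In the antioxidant response (adjusted p = 0.751) 3 of 35 were higher and 1 lower in the authors' deposited table and over the list alone. Srxn1 rose from 37.8 to 83.3 FPKM, Gpx3 from 163.6 to 350.5 FPKM and the cystine transporter gene Slc7a11 from 0.119 to 0.980 FPKM, and Nqo1 fell from 12.9 to 6.70 FPKM. The call of Nqo1 was lost under another filter setting. PPAR targets (adjusted p = 0.401) had 4 higher and 1 lower of 24 in the authors' deposited table and over the list alone. Ppargc1a, a coactivator of mitochondrial genes, rose from 0.0701 to 1.13 FPKM, Ppard from 7.98 to 17.0 FPKM and Vldlr from 4.66 to 9.36 FPKM, and the lipase gene Lpl fell from 60.1 to 30.3 FPKM. Among 49 lysosome genes (adjusted p = 0.595) the authors' deposited table had 1 higher, Ctsh, from 0.722 to 2.30 FPKM, and none adjusted over the list alone. Ctsh also lost its call under another filter setting. The abundant members Psap and Cd63 stood at 587.6 and 536.6 FPKM with GFP and 539.0 and 461.0 FPKM with p16.

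Markers of other islet and pancreatic cells were measured in the same sorted cells. Delta and PP cell markers rose, with 4 higher of 10 in the authors' deposited table and 5 higher adjusted over the list alone (adjusted p = 0.00053). Their median log2 ratio was 0.77, or 0.29 with quantile normalization on the log2(FPKM + 1) scale. This changed the pseudocount and the normalization at once, so the drop cannot be given to either. The somatostatin gene Sst rose from 1244 to 2678 FPKM, the pancreatic polypeptide gene Ppy from 344.8 to 672.0 FPKM and the retinol-binding protein gene Rbp4 from 50.5 to 101.6 FPKM, beside Pyy. Alpha cell markers did not pass (adjusted p = 0.227), with 1 of 16 higher in the authors' deposited table and over the list alone. The glucagon gene Gcg stood at 1642 and 2263 FPKM and Tmem27 at 1040 and 852.2 FPKM in GFP and p16. Duct cell markers rose (adjusted p = 0.00269), with 4 higher and 1 lower of 13 in the authors' deposited table and 5 and 1 adjusted over the list alone. Their median log2 ratio was 0.59, or 0.33 with quantile normalization on the log2(FPKM + 1) scale. Cldn4, a tight junction gene, rose from 143.3 to 486.5 FPKM, Spp1 from 3.85 to 15.1 FPKM and Clu from 88.8 to 157.8 FPKM, while the keratin gene Krt19 fell from 5.75 to 1.79 FPKM. At a preset correlation of 0.1 the duct list's adjusted p was 0.0535.

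Stellate and fibroblast markers were near 0 in the GFP group. Of 22 members listed above 0 the authors tested 6, of which 2 were higher in the authors' deposited table and 5 adjusted over the list alone. The list test passed on the 6 tested members (adjusted p = 0.000137) but not with the others included at a signed quantile of 0 (adjusted p = 0.0509). The median log2 ratio of the 6 was 3.18, or 0.60 with quantile normalization on the log2(FPKM + 1) scale. For values this near 0 the added 1 shrinks ratios by itself, so the drop is not that of the normalization alone. The collagen gene Col1a2 rose from 0.0837 to 1.597 FPKM and the decorin gene Dcn from 0.133 to 2.29 FPKM. Col1a1, Col3a1 and Sparc, named after their values were seen, stood at 0.0456, 0.169 and 0.730 FPKM with GFP and 0.343, 0.186 and 1.44 FPKM with p16. The authors did not test Col1a1 and Col3a1, and Sparc did not pass in the authors' deposited table (q = 0.238). Acinar markers did not pass (adjusted p = 0.751), with none of 23 called in the authors' deposited table or over the list alone and Ctrb1 at 6.58 and 6.20 FPKM and Cela1 at 3.02 and 5.30 FPKM. In leukocyte markers (adjusted p = 0.512) 1 of 8 was higher in the authors' deposited table and over the list alone, Cd68, from 0.229 to 1.95 FPKM. Cd68 passed narrowly (q = 0.0498 in the authors' deposited table) and lost its call under another filter setting. The macrophage gene C1qa stood at 25.9 and 35.1 FPKM and Cd79a at 7.41 and 5.50 FPKM. In Schwann cell markers (adjusted p = 0.788) 1 of 7 was higher in the authors' deposited table, Mbp, from 28.3 to 52.3 FPKM, with 1 higher and 1 lower adjusted over the list alone. Pmp22 stood at 13.5 and 9.76 FPKM. Endothelial and erythroid markers had 3 and 1 tested members, too few for the list test, and none was called in the authors' deposited table. Ramp2 stood at 8.92 and 9.93 FPKM, Esam at 2.49 and 3.04 FPKM and the haemoglobin gene Hbb-bs at 12.2 and 22.4 FPKM. Hbb-bs did not pass (q = 0.161 in the authors' deposited table). As the only tested erythroid member, its p of 0.01685 in the authors' deposited table is left unadjusted over the list alone, so that count holds no evidence. Epb4.2, not tested by the authors, stood at 0.169 and 0.300 FPKM.

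**Figure D3:**
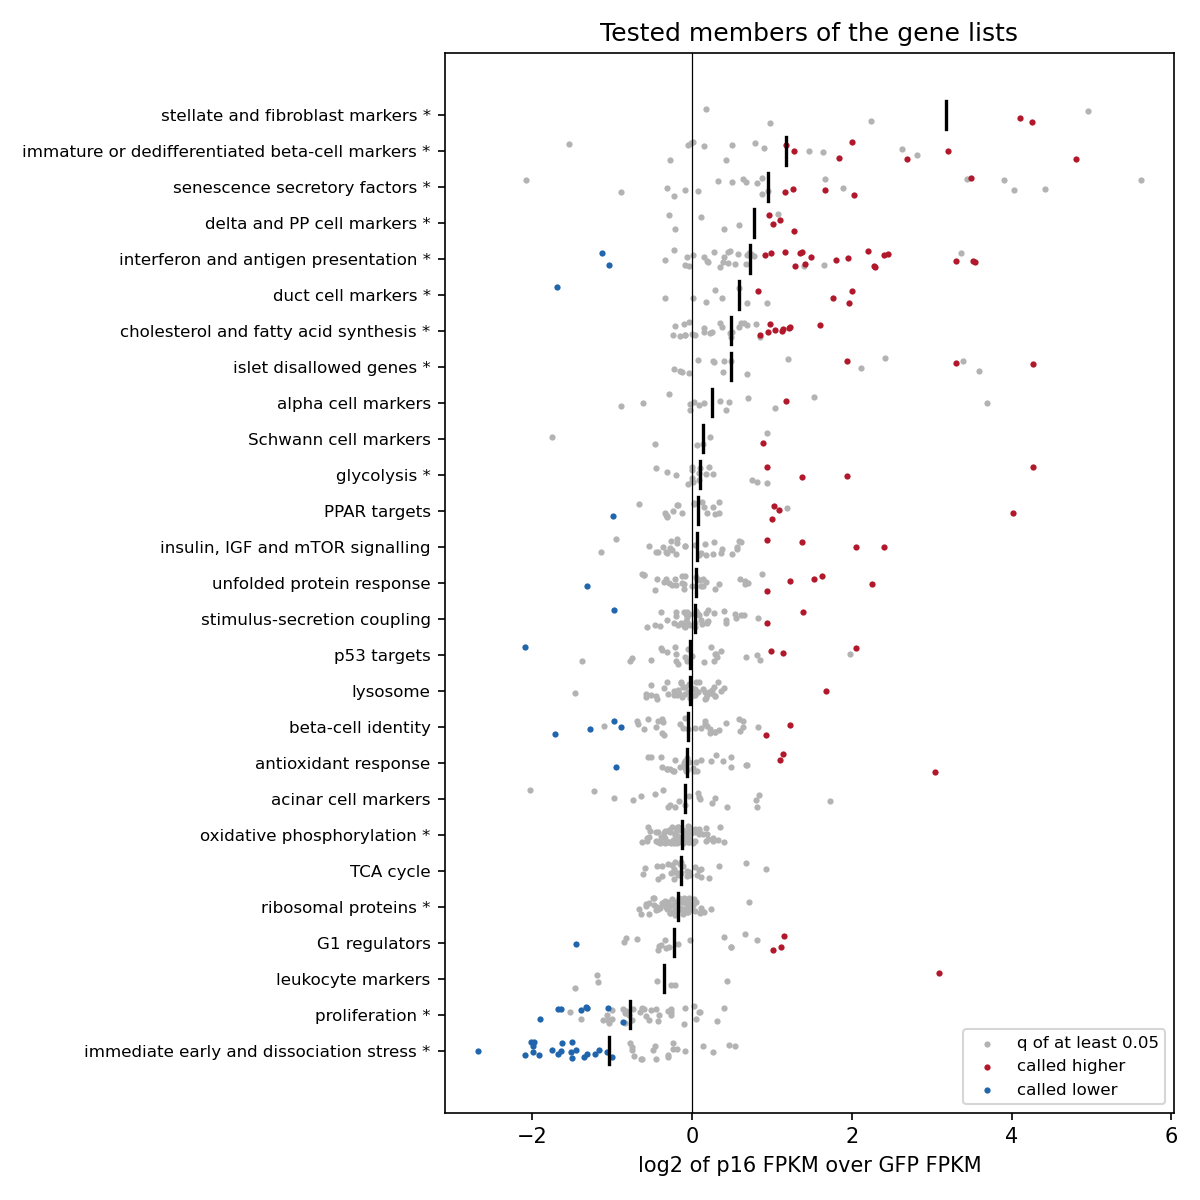
Points give the log2 of p16 over GFP FPKM for the tested members of each fixed gene list with finite values, red for genes called higher, blue for genes called lower and grey for the others. Black bars are list medians, and an asterisk marks an adjusted p below 0.05 in cameraPR; the immediate early list lies lowest, at -1.03, and the proliferation list next, at -0.77.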

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

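Alternatives with a pseudocount of 1, a mean FPKM of at least 1, other preset correlations, the authors' test score, untested genes included or the GC and length trend removed were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per group. For the same reason eBayes without trend or robust, sample weights, leaving out a sample, fry, an estimated correlation and count tools were not run. Other scalings could not be tested again; median-of-ratios and rescaling without the top 20 genes moved all log2 ratios by 0.042 and 0.088, too little to turn any call, so they show no stability. Cdkn2a FPKM kept a q below 0.05 under each filter on mean FPKM, the settings in which its p was adjusted again; its log2 ratio of 5.72 was 2.81 with a pseudocount of 5. Of 115 other genes selected for naming, 106 kept their side of the threshold and of 0 in the settings that tested them. A gene below a filter had no test there and counts as kept. At a mean FPKM of at least 1, 107 held and 2 lost their call, and at 5 or more 86 held and 1 lost it. The scaling settings adjusted no p again. Pseudocounts cannot turn the sign of a ratio, so those settings could not fail. Removal of the GC and length trend is not part of the count of 106. After it 312 of 573 higher and 62 of 146 lower calls were kept over all genes. Stmn1, Ctsh, Nqo1 and Cd68 lost their calls with other filters. Among genes not called, log2 ratios that had been below 0 became 0.0701 for Atp5e, 0.0889 for Psap and 0 for Cd63 with quantile normalization, and 0.0108 for Atp5e, 0.0240 for Rpl41 and 0.00277 for Ctrb1 with rescaling. Higher calls were 298 at a mean FPKM of at least 5, which tests fewer genes, and 311 at a q below 0.01. Lower calls were 272 at a q below 0.1, 58 at 0.01 and 90 with the trend removed. The cause of list changes was not tested. Glycolysis lost its call on ranks (0.0512), at correlations of 0.05 (0.115) and 0.1 (0.270), at a mean FPKM of at least 1 (0.0522) or 5 (0.249) and without the trend (0.0627), given as adjusted p. Oxidative phosphorylation lost it in the same settings but ranks (0.255, 0.516, 0.0519, 0.0848 and 0.185). Ribosomal proteins lost it at both correlations (0.0957 and 0.270), duct markers at 0.1 (0.0535), disallowed genes at a mean FPKM of at least 1 (0.0519) and stellate markers with untested genes included (0.0509). Lists that had not passed changed direction without the trend, stimulus-secretion coupling (0.508), insulin signalling (0.982), acinar (0.827) and Schwann (0.982), or at a mean FPKM of at least 1, acinar (0.809) and leukocyte (0.916). Of 13 called lists 7 kept their call in every setting that tested them.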

Other observations

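Tests of library scaling, of low values alone, of the share at 20 FPKM, of handling and of the share of males were chosen after their results had been seen, as were the 4 lists named next. Amino acid and one-carbon supply genes rose, with 14 higher and none lower of 45 tested in the authors' deposited table (adjusted p = 3.32e-12). Psat1, of serine synthesis, rose from 2.57 to 11.2 FPKM, beside Trib3, Sesn2 and Eif4ebp1. Actin cytoskeleton and focal adhesion genes had 23 higher and none lower of 59 in the authors' deposited table (adjusted p = 3.32e-12). Besides Vcl and Pdlim7, Fhl3 rose from 1.10 to 9.04 FPKM and Palld, which encodes palladin, from 0.310 to 5.04 FPKM.

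Tight junction and epithelial adhesion genes had 9 higher and none lower of 31 in the authors' deposited table (adjusted p = 1.7e-09). Marveld2 rose from 6.56 to 28.9 FPKM and Ocln from 17.1 to 41.2 FPKM. NF-kappaB pathway genes had 11 higher and 2 lower of 33 in the authors' deposited table (adjusted p = 0.00051, or adjusted p = 0.0512 at a preset correlation of 0.1). The pathway's members went both ways, with 20 above and 13 below their GFP value. Nfkb2 rose from 8.35 to 31.7 FPKM, while Tnfaip3, an inhibitor of the pathway, fell. These lists were drawn up on the same data and are no independent evidence of their direction.

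Rn45s, the ribosomal RNA precursor, stood at 1412 FPKM with GFP and 3612 FPKM with p16. Whether the cells or the libraries differed here was not tested. Chga, which encodes chromogranin A, is listed at 8261 FPKM with GFP and at 0 with p16, with a status that marks too many fragments.

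Higher calls outnumbered lower calls, 573 to 146. The median log2 ratio of the tested genes, -0.019, does not decide on library scaling, since the authors' scaling can have set it. With the GC and length trend removed 81.1% of the genes past the same size were higher, which argues against that trend alone as the whole cause, although 261 of the higher calls were no longer past that size. Low values stay open, alone and with the trend: at a mean FPKM of at least 5 the share was 73.4% of the calls and 74.3% with the trend removed, but at 20 or more it was 63.0% and 60.2%, and at 100 or more 35.3% of the calls. A bound of 70%, set beforehand for both together at 5 FPKM, was met, but the share went on falling above that level, so it does not exclude them, and an effect of the transgene stays open too.

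Immediate early genes were lower with p16. The GC and length trend is argued against, since the list's adjusted p after its removal was 3.26e-33. A difference in how the islets of the groups were handled could lower heat shock genes too, and the median log2 ratio of 5 such members was -1.91, with 3 of them called lower in the authors' deposited table. These were Dnajb1, whose ratio is that median, and the near-identical copies Hspa1a and Hspa1b, so they are not 3 separate signals. Hspa8 and Hsph1 were not called. Handling and transgene cannot be told apart, because each sample belongs to 1 group and values per sample were not used here.

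Xist, expressed from the inactive X chromosome of females, rose from 3.50 to 9.56 FPKM, and Y-linked genes were lower with p16. Eif2s3y fell from 23.3 to 8.87 FPKM, and Ddx3y, Uty and Kdm5d, which did not pass, stood at 24.5, 6.32 and 2.87 FPKM with GFP and 11.5, 3.17 and 1.39 FPKM with p16. The log2 ratios of these 4 genes spanned 0.39, which is consistent with a smaller share of males in the p16 group. With the GC and length trend removed their median signed quantile went from -2.50 to -1.69, which argues against that trend as the whole cause. No sex is given in the labels, so what sex adds to other calls stays untested.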
